A study of Homo sapiens with 2 samples.

How the data were processed

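RNA sequencing was available for 2 libraries, each made from 3 µg of total RNA of cells taken on day 4 of cardiac differentiation of the human embryonic stem cell line H1, an established line. Per the labels' protocols, cells were differentiated as a monolayer with small molecules, RNA was taken up in TRIzol, and libraries were sequenced on an Illumina HiSeq instrument. The library titled CTR is labelled wild type and the library titled TKO is labelled as a triple knockout of the MIR148A family. There was 1 library per group, so no difference between them has a replicate check, and neither p-values nor numbers of significant genes were computed.

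Per the submitters' processing notes, CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build hg19 were used. The annotation release, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of FPKM values (reads per kilobase of exon, scaled to the number of assigned reads of the library) with 58302 rows and a column for each library, named by the library's title. Rows carry gene symbols and no identifiers or coordinates, and 1870 rows share their symbol with another row, mostly families of short RNAs. A further 27 rows carry a date in place of a symbol, as a spreadsheet writes for some gene names, and 17 of them passed the expression filter; no gene was named from such rows. Of all rows, 94.8% matched a symbol of GENCODE release 29, whose build is GRCh38. That annotation supplied gene type, chromosome, exon length and 3' UTR sequence only, and no coordinates are given because the builds differ.

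The table holds no counts, but the depth could be recovered. The deposited FPKM of a gene multiplied by its summed exon length was a whole multiple of 1 step per library, as it is when whole reads are counted. Of the genes above 0 with a known exon length, 94.6% in the library labelled CTR and 94.5% in the library labelled TKO came within 0.05 reads of a whole number. The steps correspond to 24939789 and 24221359 assigned reads. Reads were taken as known for rows that were whole in both libraries, which held for 12663 of 13867 expressed rows (91.3%). The same rule was used for named genes below the expression filter. For rows that were not whole no read counts or intervals are given. As the strand setting is not known, reads of overlapping genes cannot be told apart. For these genes the 95% interval of the ratio between the libraries was computed by the exact Clopper-Pearson method. Such intervals, and the limit of 3 reads used where a gene had 0 reads, cover counting error only, not the spread between cultures.

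The comparison was log2((FPKM labelled TKO + 1)/(FPKM labelled CTR + 1)), with a pseudocount of 1, for genes with a mean FPKM of at least 1 over both libraries. This scale understates the difference of genes with low values. A gene was counted as higher or lower when the FPKM plus 1 differed at least 2-fold. No rescaling was applied, because the median log2 ratio of expressed genes was -0.02. The 35 gene lists and the rule for naming genes were fixed before the data were examined. For each with at least 5 expressed members, the median log2 ratio was set against 10000 random lists of the same size matched on mean FPKM in 20 bins. A list outside the central 95% of these medians (below percentile 2.5 or above 97.5) is described as below or above it. Such a percentile describes these libraries; it is not a p-value, and because genes of a list are regulated together it says nothing about replicate cultures. There were 33 lists with enough members. Lists share members: DLL1, for example, stands in those of paraxial mesoderm, Notch components and reported microRNA targets.

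For the microRNA comparison, the longest annotated 3' UTR of each expressed protein-coding gene was searched for the 8-base site TGCACTGA, which pairs with the seed shared by miR-148a, miR-148b and miR-152. The median of the site genes was set against 10000 random gene sets matched on mean FPKM and 3' UTR length (10 bins each), and against 398 other sites with the same bases in another order. Genes without an annotated 3' UTR were not searched.

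The rule for naming genes took the 12 protein-coding genes highest and the 12 lowest by log2 ratio, up to 4 members of each list with the largest absolute ratio, the targeted microRNA genes with COPZ1 and COPZ2, DLL1, all genes of both Notch lists, and POU5F1, NANOG, T, MESP1, TBX6, GATA4, ISL1, NKX2-5 and TNNT2. The rule gave 176 genes; SOX3, FOXC2, PCDH8, GRIK3, TNFRSF11A and the protocadherin beta genes other than PCDHB5 are named in addition and were chosen after their values were seen. Some genes that the rule takes are not reported here. Other settings were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, rescaling, TPM, other thresholds, bins and site definitions. Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. They were tested on simulated data with reads drawn for 54714 genes from the real means. All read counts were recovered exactly, which follows from using the same exon lengths in both steps and does not test those lengths. The 2-fold rule found 90.0% of 3-fold, 92.0% of 4-fold and 88.0% of 8-fold differences but 8.0% of 2-fold ones, which the pseudocount places under the threshold. It called 38 of 13399 unchanged genes by counting error alone. Rows with a repeated symbol or no known exon length were left out of the simulation, so this number may be too low for all expressed rows. Among the measured 2-fold rows, 15 of 263 higher and 37 of 135 lower were microRNA, snRNA, snoRNA and Y RNA rows. The list comparison was tested on the measured ratios of the 2 libraries, not on simulated reads. Of random 12-gene lists, 4.3% lay outside the central range. With 0.3 added to their log2 ratios, 96.7% were found above it.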

Results

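The transcriptomes of differentiating H1 cells were compared between a culture labelled wild type and a culture labelled as lacking the 3 members of the MIR148A family, the microRNAs miR-148a, miR-148b and miR-152. Both were harvested on day 4 of cardiac differentiation, and each is represented by 1 library, so each difference is between these 2 libraries and has no replicate check. The comparison asks how gene expression in differentiating cells differs when the microRNA family is disrupted. The library labelled CTR held 24939789 assigned reads and the library labelled TKO held 24221359. The table listed 13954 and 13870 rows at 1 FPKM or above, and 13867 rows had a mean of at least 1 FPKM. The median expressed gene carried 726 reads in the library labelled CTR and 697 in the library labelled TKO. Across these genes, which are not independent replicates, the log2 values of the libraries had a Pearson r of 0.97.

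Reads at MIR148A did not show a loss in the library labelled TKO. This gene, which lies outside any other annotated gene on chromosome 7, had 1 read (0.590 FPKM) in the library labelled CTR and 10 reads (6.07 FPKM) in the library labelled TKO, a ratio of 10.3 with a 95% counting interval from 1.46 to 447. An edit inside the hairpin could leave the primary transcript in place, so these reads cannot settle whether the label holds. The libraries are therefore named by their labels throughout. MIR148B, inside introns of COPZ1 and AC078778.2 on chromosome 12, had 1 read and 0 reads, and MIR152, inside an intron of COPZ2 on chromosome 17, had 0 reads in both, which allows up to 3 reads in each. These annotated genes are 68, 99 and 87 bases long. The labels describe no small-RNA preparation, so mature microRNAs were not measured and their loss was not checked. The host gene COPZ1, a coatomer subunit, stood at 30.4 and 30.3 FPKM. COPZ2 had 10 reads in the library labelled CTR and 4 in the library labelled TKO.

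Neural genes were higher, and endoderm, epithelial and cardiac transcription factor genes lower, in the library labelled TKO. The direction rests on labels that the MIR148A reads did not bear out, though they cannot settle whether the labels hold. Counts of genes or list members at 2-fold are on the log2(FPKM + 1) scale throughout, whereas a fold given for a gene is the ratio of its FPKM values with no pseudocount, so a gene with low values can pass 2-fold in the ratio and not in the count. At least 2-fold higher there were 263 rows and at least 2-fold lower 135 rows, of which 201 and 57 were protein-coding genes. The 12 protein-coding genes with the highest ratio included FGFBP3, an FGF-binding protein, at 15.4 FPKM in the library labelled CTR and 102.5 in the library labelled TKO, 6.65-fold higher (95% counting interval 6.22 to 7.13). GBX2, a homeobox gene of the neural plate, was 6.66-fold higher (5.98 to 7.42), POU3F1, a POU factor of neural progenitors, 7.46-fold higher (6.34 to 8.83), and SOX21 5.35-fold higher (4.97 to 5.78). WNT8B, a Wnt ligand of the developing brain, had 13 and 248 reads. TCEAL2 had the highest ratio, with 0.385 and 11.8 FPKM, 30.6-fold (18.6 to 53.9). PIPOX, VGLL3, DLK1, EGR1 and VGF were between 5.67-fold and 8.31-fold higher. At the other end, TSPYL5 had 593 reads in the library labelled CTR and 0 in the library labelled TKO, at least 192-fold lower when 0 is taken as up to 3 reads, with a 95% counting interval that starts at 156-fold. PCDHB5, a clustered protocadherin, was 7.07-fold lower (6.29 to 7.97), CTSF, cathepsin F, 11.0-fold lower (7.79 to 16.0), SLC28A2, a nucleoside transporter, 10.01-fold lower (7.28 to 14.1) and SLC39A4, a zinc transporter, 5.91-fold lower (5.09 to 6.89). ZNF649, SHISA3, C9orf64, CD177 and EGFLAM were between 3.04-fold and 5.98-fold lower, and the remaining 2, HAND1 and SP5, belong to lists described below. The numbers of genes depend on the pseudocount and the expression filter. With a pseudocount of 0.1 they were 436 and 322, and in TPM with a minimum of 1 TPM, which admits 19608 rows, they were evenly split at 791 and 795.

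**Figure D1:**
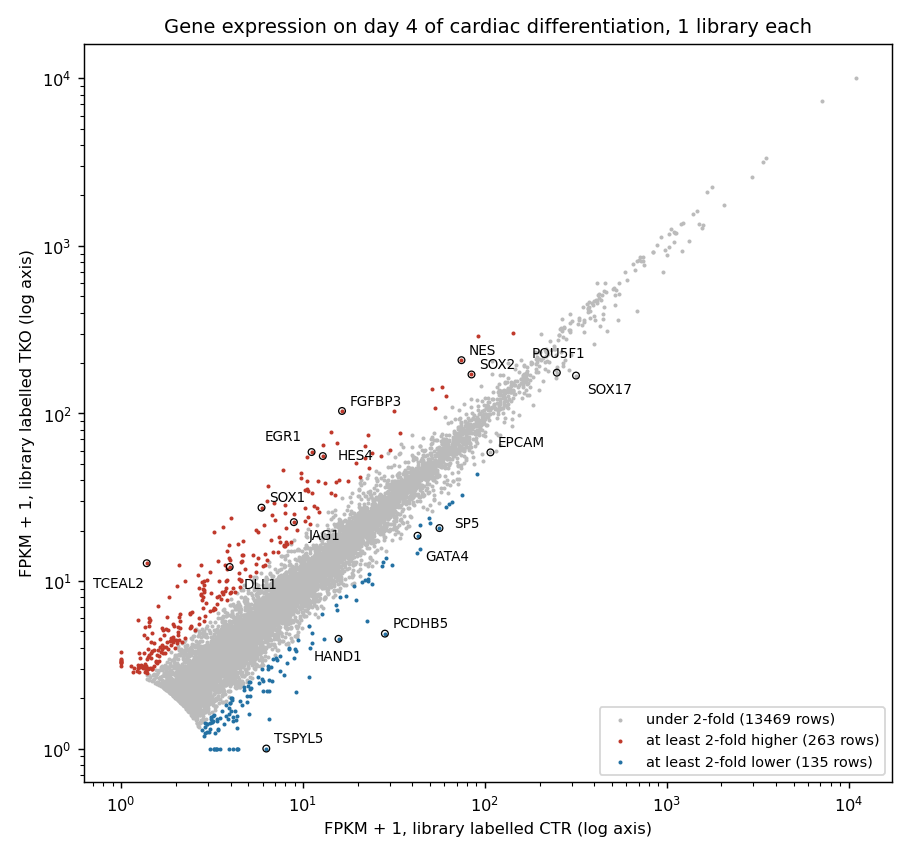
FPKM plus 1 of the 13867 expressed rows in the library labelled CTR (horizontal, log axis) and the library labelled TKO (vertical, log axis), 1 library each; every point is a row and circled points are named genes. The 263 rows at least 2-fold higher lie above the diagonal cloud and include FGFBP3, SOX1 and DLL1; the 135 at least 2-fold lower include TSPYL5, PCDHB5 and HAND1.

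Neural ectoderm genes were higher as a group in the library labelled TKO. The 8 expressed members of the list had a median log2 ratio of 1.41, above all 10000 matched random lists, whose central 95% ran from -0.21 to 0.16. Of these members 5 were at least 2-fold higher in the library labelled TKO, none was 2-fold lower, and 7 had a ratio above 0. With no expression filter the median over 13 members was 0.63, and with a pseudocount of 5 it was 0.65, both above all random lists. SOX1, the early neural plate factor, was 5.36-fold higher (95% counting interval 4.78 to 6.03), at 4.92 and 26.4 FPKM. NES, the intermediate filament nestin of neural progenitors, was 2.82-fold higher (2.76 to 2.88), at 73.4 and 207 FPKM. The forebrain genes LHX2 and FEZF1 were 5.41-fold (3.89 to 7.68) and 6.27-fold (4.55 to 8.84) higher, each with under 1 FPKM in the library labelled CTR. SOX3, the remaining member at 2-fold, named after its values were seen, was 2.68-fold higher (2.49 to 2.89). SOX2, counted in the pluripotency list and also a neural progenitor gene, was 2.03-fold higher (1.97 to 2.10). Of the 8 expressed neural crest genes, 3 were at least 2-fold higher and none was 2-fold lower, with a median of 0.70 (0.30 with a pseudocount of 5), also above all random lists. These 3 were NGFR, 4.32-fold higher (3.81 to 4.91), SOX9, 4.20-fold higher (3.57 to 4.97), and PAX3, at 0.372 and 2.09 FPKM. SNAI2, at 3.04 and 6.22 FPKM, was under the threshold on the log2(FPKM + 1) scale. The immediate early and heat shock list, of genes that respond to signals and to handling, was also higher in this library, with a median of 1.04.

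Definitive endoderm and epithelial genes were lower as groups. All 15 expressed epithelial genes had a ratio below 0, with a median of -0.69 (central random range -0.15 to 0.11), though none reached 2-fold on the log2(FPKM + 1) scale. Among them CDH1, E-cadherin, was 1.81-fold lower (95% counting interval 1.74 to 1.88), EPCAM 1.85-fold lower (1.77 to 1.92), the claudin CLDN4 1.99-fold lower (1.86 to 2.14) and GRHL2, an epithelial transcription factor, 2.46-fold lower (2.12 to 2.86). Of 17 expressed endoderm genes, 14 had a ratio below 0 and the median was -0.49 (central random range -0.14 to 0.09; -0.27 with a pseudocount of 5); no member reached 2-fold in either direction. SOX17, the endoderm regulator, was at 316 FPKM in the library labelled CTR and 167 in the library labelled TKO, 1.89-fold lower (1.84 to 1.94). GSC went the other way at 2.06-fold higher (1.76 to 2.42). PRDM1 stood at 7.03 and 3.22 FPKM. The immediate early and heat shock list, median 1.04, was higher in the same library.

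The pluripotency list lay below its random range with a median of -0.30 (percentile 0.0, range -0.13 to 0.09; -0.18 with a pseudocount of 5), and 16 of its 22 expressed members had a ratio below 0. POU5F1 was 1.42-fold lower (95% counting interval 1.39 to 1.46). It stood at 247.9 FPKM in the library labelled CTR and 174.2 in the library labelled TKO. The Nodal co-receptor TDGF1 was 1.63-fold lower (1.58 to 1.69), at 119.5 and 73.27 FPKM. Both were far above NKX2-5, at 2.489 and 1.498 FPKM, and TNNT2, at 0.4088 and 0.6654. Other genes went the other way, with GATA4 at 41.68 and 17.63 FPKM and NANOG at 1.138 and 1.294. How far either culture had moved toward cardiac cells was not tested. NANOG had 153 and 169 reads, and its interval included equality (0.91 to 1.42). PRDM14 was 2.15-fold higher (1.83 to 2.53). Primitive streak genes had a median of -0.28 (percentile 0.1), with 2 of 12 at least 2-fold lower and 1 higher. SP5, a Wnt-induced factor, was 2.81-fold lower (2.61 to 3.02) and MESP2 3.21-fold lower (2.37 to 4.41), EOMES was 1.83-fold lower (1.72 to 1.94), and WNT3A was 3.10-fold higher (2.72 to 3.53). T, the gene of brachyury, was near the floor at 0.763 and 0.503 FPKM. Nodal target genes had a median of -0.37 (percentile 0.1, 8 members, none at 2-fold), and the amnion and trophoblast genes a median of -0.42 (percentile 0.5, 5 members, none at 2-fold), where GATA3 stood at 113.8 and 58.4 FPKM. With no expression filter, the medians of primitive streak genes (-0.15) and of amnion and trophoblast genes (0.0) lay inside their ranges. Nodal target genes lay inside with a pseudocount of 5 (-0.13) and by the mean (-0.21).

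Cardiac transcription factor genes that passed the expression filter had a median of -1.01 (percentile 0.0, central random range -0.20 to 0.14). With no filter the median over 18 members was -0.32, and with a pseudocount of 5 it was -0.61, both at percentile 0.0. Of 8 expressed members, 4 were at least 2-fold lower in the library labelled TKO, none was 2-fold higher, and 7 had a ratio below 0. HAND1 was 4.18-fold lower (95% counting interval 3.49 to 5.03), GATA5 3.27-fold lower (2.60 to 4.15), GATA4 2.36-fold lower (2.24 to 2.5) and TBX3 2.31-fold lower (2.18 to 2.45), beside the immediate early and heat shock list median of 1.04. ISL1, a gene of the second heart field that also stands in the amnion and trophoblast list, was 1.98-fold lower (1.75 to 2.25). NKX2-5 was scarce in both libraries, with 130 and 76 reads, 1.66-fold lower (1.24 to 2.23). The wider list of cardiac and lateral plate mesoderm had a median of -0.19 (percentile 0.8), with HAND1 of its 14 members 2-fold lower on the log2(FPKM + 1) scale and BMP5 2-fold higher. BMP5 was 7.25-fold higher (5.30 to 10.2) from 45 reads. MESP1, the early cardiac mesoderm factor, had a log2 ratio of -0.94 on that scale, under the threshold, and an FPKM ratio 2.59-fold lower (1.99 to 3.40). Without HAND1, the expressed gene it shares with the cardiac list, the median of this list was -0.16, inside its range at percentile 3.2, as it was by the mean, -0.11, or with no expression filter, -0.073. The sarcomere and cardiomyocyte list went both ways. Its median was 0.24 (percentile 99.8), with 2 of 11 members 2-fold higher and 1 lower. Desmin (DES) was 4.81-fold higher (3.36 to 7.07), cardiac actin ACTC1 stood at 6.53 and 16.2 FPKM, and TNNC1 was 2.19-fold lower (1.93 to 2.5). TNNT2 was below 1 FPKM in both libraries, with 74 and 117 reads, 1.63-fold higher (1.21 to 2.21). By the mean, 0.12, or with no expression filter, 0.042, this list lay inside its range. The lower cardiac transcription factor genes therefore do not by themselves show a lower cardiac programme. Among genes that passed the filter, the definitive endoderm (median -0.49) and amnion and trophoblast (-0.42) lists were lower in the same library. Whether the lower transcription factor genes reflect cardiac cells or those other cell types was not tested.

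Paraxial and presomitic mesoderm genes lay above their random range, with a median of 0.21 (percentile 99.9). Of 16 expressed members, 4 were at least 2-fold higher and 2 at least 2-fold lower. The higher ones were DLL1, WNT3A, PAX3 and FOXC2, and the lower ones MESP2 and PCDH8, of which FOXC2 and PCDH8 were named after their values were seen. PCDH8 was 2.26-fold lower (95% counting interval 2.04 to 2.5), and FOXC2 stood at 0.615 and 2.33 FPKM. TBX6, a presomitic regulator, had 90 and 121 reads, 1.38-fold higher (1.05 to 1.84). With a mean FPKM of at least 5, 10 members remained and the median of 0.039 was inside the range. PAX3 also stands in the neural crest list, which was higher in the same library (median 0.70), as was the neural ectoderm list (1.41). Whether the higher members reflect paraxial mesoderm or neural cells was not tested.

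The Notch ligand genes DLL1 and JAG1 and the Notch target gene HES4 were at least 2-fold higher in the library labelled TKO, while 6 of the 7 expressed Notch targets and 16 of the 19 expressed pathway components were under 2-fold on the log2(FPKM + 1) scale. DLL1, a Notch ligand, had 238 reads in the library labelled CTR and 870 in the library labelled TKO, at 2.96 and 11.1 FPKM, 3.76-fold higher (95% counting interval 3.26 to 4.36). JAG1 stood at 7.92 and 21.5 FPKM, and JAG2 was 1.51-fold higher (1.31 to 1.75). DTX4 was 2.18-fold higher (2.06 to 2.31) and MFNG, under the threshold on that scale, stood at 0.804 and 1.72 FPKM. DLL3 had an interval that included equality (0.96 to 1.31), and DLL4 had 8 and 12 reads. Of the receptors, NOTCH1 stood at 20.3 and 32.3 FPKM, NOTCH2 was 1.15-fold lower (1.11 to 1.20), and NOTCH3 was at 76.5 and 78.1 FPKM. The transcriptional mediator RBPJ was at 10.8 and 10.9 FPKM, and the co-activator MAML1 at 19.3 and 19.4. Over the 19 expressed components the median was 0.01 (percentile 75.6), with 3 members at least 2-fold higher and none lower. The mean was 0.24, above its own random range. The 7 expressed Notch targets had a median of 0.47 (percentile 99.9), and of 0.20 with a pseudocount of 5 (percentile 99.6). In the same library the neural ectoderm list had a median of 1.41 and the immediate early and heat shock list 1.04. HES4 was 4.61-fold higher (4.09 to 5.21), HES1 2.08-fold higher (1.85 to 2.35), NRARP 1.45-fold higher (1.30 to 1.63) and DTX1 1.66-fold higher (1.35 to 2.05). LFNG was at 21.03 and 19.99 FPKM, with an interval that included equality. HES5 had 0 reads in the library labelled CTR and 17 in the library labelled TKO, at least 5.83-fold higher when 0 is taken as up to 3 reads, with an interval that starts at 4.25-fold. HEY2 went the other way, 1.73-fold lower (1.17 to 2.59). HES4 alone of the expressed targets reached 2-fold on the log2(FPKM + 1) scale.

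Genes reported elsewhere as targets of miR-148 or miR-152 lay above their random range, with a median of 0.11 over 26 expressed members (percentile 99.7). DLL1 was put on this list with the study's own interest in it in mind, so it is not independent evidence of the list's direction. Of the 26, 4 were at least 2-fold higher and none was 2-fold lower. They included DLL1 and WNT10B, the latter 3.18-fold higher (95% counting interval 2.42 to 4.21). The DNA methyltransferase gene DNMT3B was 1.05-fold lower (1.02 to 1.07). The median of the list was -0.003, inside its range, once members under a mean of 5 FPKM were left out. In every other setting run the list stayed above, for example at 0.058 (percentile 98.8) with a pseudocount of 5.

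A wider set, defined by sequence alone, lay inside its random range. Of 11441 expressed protein-coding genes with an annotated 3' UTR, 554 carried the 8-base site TGCACTGA. Their median log2 ratio was -0.04, against -0.03 for genes without it. It sat at percentile 54.8 of matched random sets, whose central 95% ran from -0.05 to -0.02. After adjustment for expression and 3' UTR length the site ranked at percentile 51.3 among 398 reordered sites. At least 2-fold higher were 10 site genes, among them TEK, and CD177, GRIK3 and TNFRSF11A, the latter 2 named after their values were seen, were at least 2-fold lower. The shares were about those of all 11495 expressed protein-coding genes, of which 201 were higher and 57 lower. DLL1 had a 7-base match only. With 0.05 added to the measured log2 ratio of every site gene, their median lay above all random sets. That is an even shift of all 554 genes, and a smaller one was not tried.

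**Figure D2:**
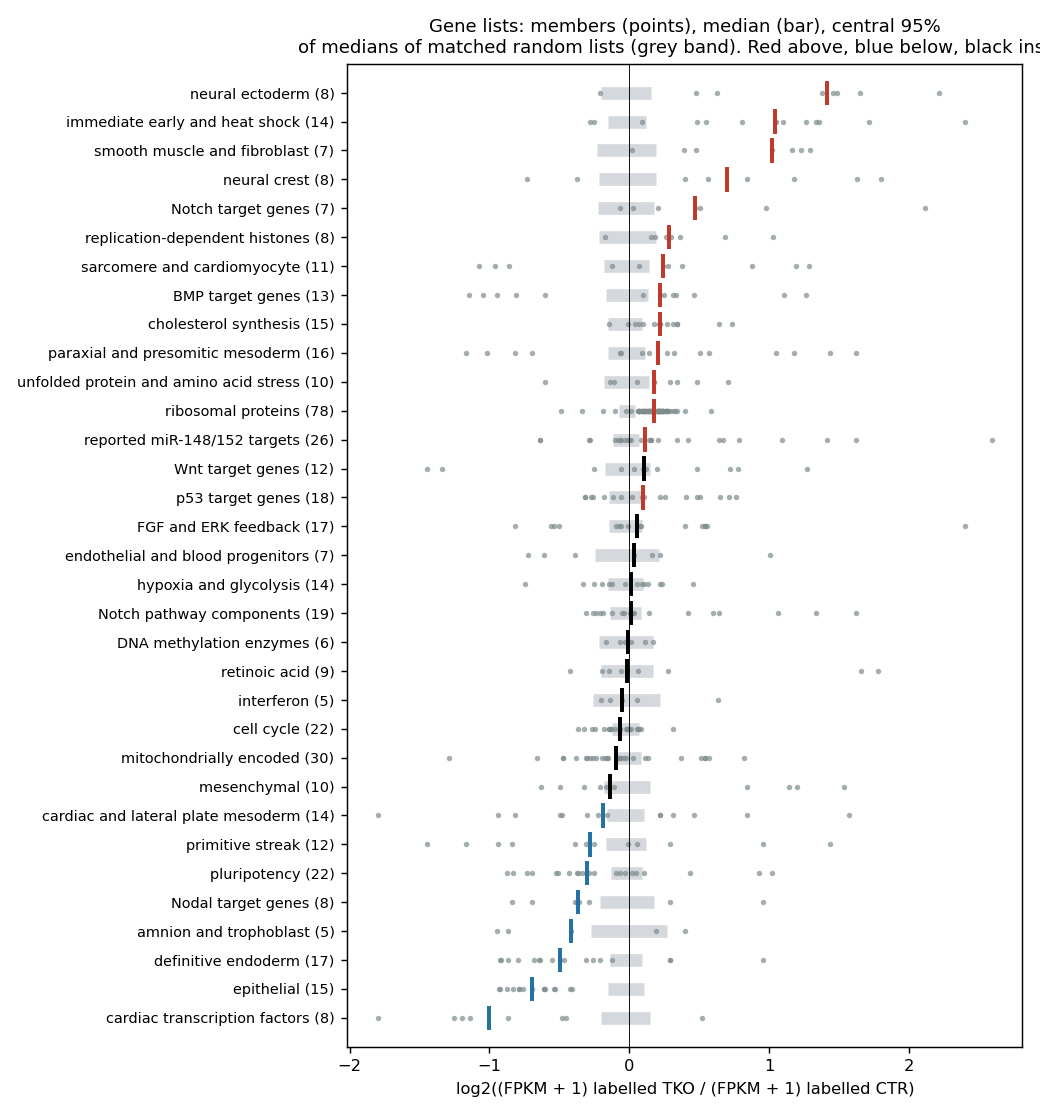
log2 ratio of FPKM plus 1, labelled TKO over labelled CTR (horizontal), for the expressed members (grey points) of each gene list (rows, with the number of expressed members), 1 library each; the upright bar is the list median, red above, blue below and black inside the central 95% of medians of matched random lists, drawn as a grey band. Among members that passed the expression filter, neural ectoderm genes have the highest median, 1.41, and cardiac transcription factors the lowest, -1.01; with no filter these medians are 0.63 and -0.32 and are not the highest and the lowest.

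The immediate early and heat shock list was higher in the library labelled TKO, with a median of 1.04 over 14 expressed members (percentile 100.0, central random range -0.16 to 0.12), and of 0.48 with a pseudocount of 5. Of these, 8 were at least 2-fold higher in the library labelled TKO and none was 2-fold lower. EGR1 was 5.69-fold higher (95% counting interval 5.28 to 6.15), JUN 3.48-fold higher (3.24 to 3.74), FOS 2.96-fold higher (2.58 to 3.41), and EGR2 had 17 and 182 reads. The FGF and ERK feedback genes had a median of 0.06 (percentile 92.9), with EGR1 alone at 2-fold. SPRY4 stood at 33.2 and 22.2 FPKM, and FGF17 was 1.83-fold lower (1.69 to 1.98). Wnt target genes had a median of 0.11 (percentile 93.8) and went both ways. CCND1, cyclin D1, was 2.47-fold higher (2.36 to 2.58), whereas SP5 and the Wnt inhibitor NOTUM, 3.50-fold lower (2.84 to 4.35), were 2-fold lower. BMP target genes were split as well, with 2 of 13 at least 2-fold higher and 2 lower. BAMBI was 2.25-fold lower (2.13 to 2.39) and SMAD6 2.12-fold lower (2.04 to 2.19), while the BMP antagonist NOG was 2.99-fold higher (2.40 to 3.74) and ATOH8 4.26-fold higher (3.34 to 5.48). The median of that list, 0.22 (percentile 99.8), and its mean, -0.04, differed in sign, and with a mean FPKM of at least 5 the median of 0.10 was inside the range. Among 9 retinoic acid genes, CRABP1, a retinoic acid binding protein, was 3.17-fold higher (3.02 to 3.33) and CYP26C1, a retinoic acid hydroxylase, 3.69-fold higher (3.44 to 3.97). The other 7 were under 2-fold, so that the median was -0.02 (percentile 50.5) and the mean 0.33, above its own random range.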

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

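The median of expressed genes was -0.02, and rescaling left every list on its side of the range. Of 257 list medians under other settings, 236 kept their position, including those of the neural, neural crest, epithelial, endoderm, cardiac transcription factor, pluripotency and Notch target lists under all settings run. Their sizes moved more, over these settings (the mean included) from 1.46 to 0.63 for neural, 1.01 to 0.30 for neural crest, -0.75 to -0.52 for epithelial, -0.56 to -0.27 for endoderm, -1.09 to -0.32 for cardiac transcription factor, -0.33 to -0.18 for pluripotency and 0.60 to 0.20 for Notch target genes. The smallest came with a pseudocount of 5, which shrinks every ratio, or, for the neural and cardiac lists, with no filter. The site genes stayed inside their range in every setting. The neural crest list kept fewer than 5 members with a mean FPKM of at least 5 and was not compared there. The same held for smooth muscle and fibroblast, amnion and trophoblast, endothelial, Wnt target, interferon and histone genes. The counts of genes at least 2-fold higher and lower, 263 and 135, were 436 and 322 with a pseudocount of 0.1, 77 and 19 with 5, 126 and 44 with a mean FPKM of at least 5, 791 and 795 in TPM, and 620 and 616 at 1.5-fold. Those lower were 236 with no filter, 57 among protein-coding genes and 72 with at least 50 reads in both libraries together, a setting chosen after the data were seen. With a pseudocount of 5, Nodal targets (-0.13) moved inside their range and mitochondrially encoded genes (-0.089) below it. With no filter, primitive streak (-0.15), cardiac and lateral plate mesoderm (-0.073), amnion and trophoblast (0.0) and sarcomere (0.042) genes moved inside. With a mean FPKM of at least 5, so did paraxial mesoderm (0.039), BMP target (0.10) and stress response (0.12) genes; reported targets turned to -0.003, and mitochondrially encoded genes lay below (-0.15, and likewise with at least 50 reads, -0.15). By means, cardiac and lateral plate mesoderm (-0.11), sarcomere (0.12), Nodal target (-0.21), p53 target (0.15) and stress response (0.14) genes moved inside, BMP targets turned to -0.04, and Notch components (0.24), retinoic acid (0.33) and mesenchymal (0.28) genes moved above. Apart from members left out, the cause was not tested. No paired analysis was possible because each group has 1 library; for the same reason no replicate could be left out. Depth limits the microRNA loci, with at most 10 reads each.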

Other observations

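The tests of explanations were chosen after the result was seen, except those of chromosomes and of microRNA sites. Contractile and matrix genes of smooth muscle and fibroblasts were higher in the library labelled TKO. So were the neural ectoderm list (median 1.41) and the immediate early and heat shock list (1.04). The values that follow are of the smooth muscle and fibroblast list. Of 7 expressed members, 4 were at least 2-fold higher and none lower, with a median log2 ratio of 1.02, above all random lists. The median was 0.26 over 12 members with no filter and 0.37 with a pseudocount of 5. TAGLN, transgelin, was 2.51-fold higher (95% counting interval 2.39 to 2.65), CNN1, calponin, 2.89-fold higher (2.43 to 3.44), COL1A1 2.38-fold higher (2.26 to 2.5) and ACTA2 4.65-fold higher (3.09 to 7.22) from 29 reads. Mesenchymal genes went both ways. VIM, vimentin, was 3.05-fold higher (2.88 to 3.23), CDH11 2.68-fold higher (2.48 to 2.91) and ZEB2 at 0.568 and 2.59 FPKM, yet the list median was -0.14 (percentile 6.9) and the mean 0.28, above its own random range. Of 7 endothelial and blood progenitor genes the angiopoietin receptor gene TEK alone reached 2-fold on the log2(FPKM + 1) scale, 2.14-fold higher (1.97 to 2.32), and CD34 was 2.49-fold lower (2.08 to 2.98), with a list median of 0.03 (percentile 69.6).

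Ribosomal protein genes were slightly higher as a group, with 73 of 78 above 0, a median of 0.17 (percentile 100.0) and none at 2-fold; RPS6 was 1.32-fold higher (1.30 to 1.34). Cholesterol synthesis genes had a median of 0.22 (percentile 100.0), with 13 of 15 above 0 and INSIG1 1.84-fold higher (1.61 to 2.10). Replication-dependent histone genes, largely lost where libraries select for poly(A), had a median of 0.28 over 8 expressed members (percentile 99.6) and 0.012 over 85 members with no filter, with HIST1H1C 2.40-fold higher (1.68 to 3.49). The stress response list of unfolded protein and amino acid genes stood at 0.18 (percentile 99.1), while HSPA5 was 1.52-fold lower (1.49 to 1.55); it lay inside its range by the mean (0.14) and with a mean FPKM of at least 5 (0.12). The p53 target genes stood at 0.10 (percentile 97.9), with BBC3 1.80-fold higher (1.62 to 2.00), and were inside by the mean (0.15). Lists inside their random range were cell cycle (-0.07), hypoxia and glycolysis (0.01), interferon (-0.05), mitochondrially encoded (-0.09) and DNA methylation enzyme (-0.01) genes. VEGFA was 1.71-fold lower (1.66 to 1.75), and the mitochondrial tRNA gene MT-TE, the member at 2-fold, had 5 and 1 reads. Intermediate mesoderm and HOX genes had 2 and 1 expressed members, too few for a median. HOXA2 was the expressed HOX gene, at 0.555 and 2.27 FPKM.

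Other protocadherin beta genes were looked at after PCDHB5 was seen among the lowest genes, and were not compared with random lists. PCDHB16 was 8.32-fold lower (5.85 to 12.2), PCDHB3, PCDHB15 and PCDHB2 were between 1.36-fold and 1.81-fold lower, and PCDHB10 had 136 and 119 reads, a ratio of 0.90 with an interval that included equality (0.70 to 1.16).

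The first pattern is that neural genes were higher while endoderm and cardiac transcription factor genes were lower in the library labelled TKO. Against gain or loss of a whole chromosome, the median log2 ratio of 23 chromosomes, the autosomes and X, lay between -0.042 and 0.003 and the bound set beforehand was 0.3. Chromosome Y was not included, and such a median can miss a change in part of a chromosome or in part of the cells. Slower exit from pluripotency would need pluripotency genes to be higher, and their list median was -0.30, below its random range. That list shares 5 members with the Nodal target list and 2 with the epithelial list, which were themselves lower. It was not run without them. Of its 22 expressed members 16 were below 0, while SOX2 and PRDM14 were higher, so slower exit is not excluded. A culture or clone difference unrelated to the microRNAs cannot be told apart from the genotype with 1 library per group, and a changed mix of cell types remains as open as a change within cells, since the RNA is from bulk cells. The knockout itself stays open as an untested biological explanation.

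The second pattern is the higher level of immediate early genes, to which the 8 members at 2-fold of the immediate early and heat shock list belong. Sustained FGF and ERK signalling is a possible explanation, but the feedback genes without EGR1 had a median of 0.022 with members on both sides, which decides nothing. Handling of the culture before lysis cannot be told apart from the genotype either, as there was 1 harvest labelled with each.

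The third pattern is that MIR148A had more reads in the library labelled as its knockout. Against counting error of few reads, the lower bound of the ratio's interval was 1.46, though it rests on 1 read in the library labelled CTR. Differences of this kind were common among microRNA rows. Of 132 expressed ones, 7 were at least 2-fold higher and 18 lower, against 263 and 135 of all 13867 expressed rows. The rise at MIR148A is therefore not distinctive. An edit inside the hairpin could leave the primary transcript in place and unprocessed, but the 10 reads come as a count without sequence, so this stays open. Exchanged sample labels would predict lower levels of site genes in the library labelled TKO, and the intact labels higher ones; their median was -0.036, inside its range, so these genes favour neither. The list of reported targets, with a median of 0.11 at percentile 99.7, runs the way intact labels predict. It was -0.003 and inside its range with a mean FPKM of at least 5, and above its range in every other setting run. As 1 setting loses the shift, an exchange stays open.

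The hypothesis that loss of the shared seed raises its predicted targets as a class had its prediction set before the result was seen. The test found no shift, with the 8-base site genes at percentile 54.8 of matched sets. With genes that hold the 7-base site TGCACTG added, the median of 1850 genes was -0.04, at percentile 16.1 of their own matched sets. Genes with only the other 7-base site, GCACTGA, were not included. Of the 1850 genes, 38 were at least 2-fold higher and 5 lower, against 201 and 57 of all 11495 expressed protein-coding genes. These counts were not set against matched sets. The medians speak against a broad shift of genes with such sites between these libraries on day 4, and not against an effect on single targets such as DLL1. Mature microRNAs were not measured in either library, and an exchange of labels stays open. The result therefore cannot decide whether loss of the seed raises its targets.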
